A study of Mus musculus with 4 samples.

How the data were processed

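Gene expression was measured in tumour-associated macrophages sorted from mouse GIST tumours, with 2 arrays of a vehicle pool and 2 arrays of an imatinib pool (8 mice per group, 2 weeks of treatment, 600 mg/L imatinib in drinking water, 200 ng of RNA per array, per the labels). The deposited table holds microarray signal intensities on a linear scale, made by the authors with the MAS5 algorithm in Affymetrix Expression Console, per the submitters' processing notes; versions and settings are not given in the sources used here. MAS5 subtracts background and scales each array to a common trimmed mean, and the mean after trimming 2% at each end was 500 on all 4 arrays (500.3 on each). Such a scaling ties all genes to the brightest part of the array, so a change in abundant transcripts shifts the others, and dim signals are noisy after background subtraction. Detection calls were not used here.

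Of 22690 probe sets, 64 were controls and were left out of the tests. Of the other 22626, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. Only probe sets with 1 symbol were named, which gave 12393 genes. Gene symbols were checked by Entrez gene ID against the RefSeq table of assembly GRCm38.p6, used for names only; 20351 probe sets matched and 0 symbols had to be updated. No coordinates are given because the sources used here name no genome build.

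Signals were transformed as log2(signal + 32), so that a fold change is on that scale and understates changes of dim genes. Genes were represented by their brightest probe set with 1 symbol and were tested if its mean lay at or above the 40th percentile of all probe sets without controls (a signal of about 79.8). The groups were compared with limma (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05; the prior had 8.71 degrees of freedom and the residuals 2. Folds and log2 differences are imatinib over, or minus, vehicle; errors of signals are SD and errors of log2 differences are SE. Of 498 called genes with several probe sets above the filter, all probe sets moved the same way in 409, and 3 had a probe set past the threshold the other way. Analyses used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

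The 23 process lists and 15 cell type marker lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The lists hold 696 entries, of which 628 were on the array. Each list with at least 5 tested members was compared with all other tested genes by limma's camera at a preset correlation of 0.01, with adjustment over the 33 lists. Alternatives were camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes. With an estimated correlation camera rests on the 2 residual degrees of freedom. Hardly any list can then pass after adjustment, whatever its correlation. The genes named are the 10 with the largest increase and the 10 with the largest decrease among called genes with separated arrays and with established names, up to 4 called members of each list by size of change (or up to 2 bright members where none was called), and 18 genes fixed in advance. Mfge8, Ldha, Cox5b, Mcm2, Cxcl12, Mmp12, Fn1 and Serpinf1 fall outside this rule and were chosen after their values were seen, to complete small counts, as were the genes that only the closing section names.

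The procedure was tested on simulated arrays with the signal levels and spread of these 8145 genes: it called 19% of 100 genes changed by 0.5 on the log2 scale, 74% of 100 genes changed by 1, and 3 unchanged genes. Small changes were therefore often missed in the simulation. Far fewer genes changed in it than were called in the data, which makes its adjusted threshold stricter, so these shares do not carry over directly. Alternatives were a smaller (1) and a larger pseudocount, no filter and a 60th percentile filter, quantile normalization, equal array medians, the mean of a gene's probe sets, each probe set on its own, leaving out probe sets that may hit several transcripts, no variance trend, a robust prior, limma's treat against 1.2-fold, the replicate number as a block, and each array left out in turn. Equal macrophage identity markers across arrays was added after seeing the data.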

Results

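Tumour-associated macrophages were sorted by flow cytometry from the tumours of mice that develop gastrointestinal stromal tumour (GIST), a sarcoma of the gut wall that is usually driven by an activated Kit receptor tyrosine kinase. The mice had received vehicle or imatinib, an inhibitor of Kit, Pdgfr, Abl and Csf1r kinases, at 600 mg/L in the drinking water for 2 weeks. By the design text, cells of 8 mice per group were pooled and each pool was measured on 2 Affymetrix expression arrays from 200 ng of RNA, which gave 2 vehicle and 2 imatinib arrays. The design text describes the arrays of a group as duplicates of a pool while the sample titles call them biological replicates. The p-values of single genes therefore measure only the spread between arrays, which may be technical. Those of camera at the preset correlation and of the Fisher and permutation tests rest mainly on the spread across genes. If each group was 1 pool, none of them measures the spread between pools. The number of arrays limits the precision. The median signal was 152.4 and 141.5 on the vehicle arrays and 122.3 and 133.7 on the imatinib arrays. Pearson's r across probe sets, which are not independent replicates, was 0.981 and 0.984 within the groups and 0.968 to 0.972 between them. The ratio of 3' to 5' signal of the Gapdh control probe sets, a measure of RNA integrity and labelling, was 2.91 and 2.76 with vehicle and 2.34 and 2.09 with imatinib, and that of beta-actin was 3.99 and 3.58 against 3.06 and 2.71.

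The comparison asked how imatinib treatment of the tumour-bearing mice changed gene expression in the sorted macrophages. Among the 10 largest increases were Adamdec1, a secreted metalloprotease of gut macrophages (signal 1289 ± 17.4 with vehicle and 6016 ± 4.26 with imatinib, SD, n = 2, 4.58-fold), Clec4n, which encodes the fungal receptor dectin-2 (3.28-fold), and Pla2g7, a platelet-activating factor hydrolase (3.22-fold). The dimmer genes Cd4 (4.85-fold), Clec1b (4.67-fold), Ctsf (3.73-fold), Adgre4 (3.65-fold), Spic (3.46-fold), Abcg3 (3.29-fold) and Klra17 (2.86-fold) completed this set. Klra17 belongs to a family of near-identical receptors, so its identity is uncertain. The 10 largest decreases were Krt19, a keratin of simple epithelia (2346 ± 340.5 to 289.6 ± 64.7, log2 difference -2.89 ± 0.15, SE), followed by Ttr, Slc6a14, the desmosomal gene Dsp, Sult1b1, Oit1, Lypd8, Cyp2c65, Tspan8 and Prom1, with log2 differences from -2.87 for Ttr to -2.47 for Prom1.

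Of 8145 genes tested with limma, 554 were higher and 711 were lower with imatinib at a Benjamini-Hochberg adjusted p below 0.05, and 49 and 316 of these differed at least 2-fold. The imatinib arrays lay on one side of both vehicle arrays for each of these calls, which a call at 2 arrays per group all but requires. They did so for 55.97% of the tested genes, where chance gives 33.33% if the 4 arrays are exchangeable. Duplicates of 1 pool per group are not, so the excess need not come from imatinib. The higher genes made up 43.79% of the calls. When the array medians were set equal, 1050 genes were higher and 492 lower, so that 68.09% of calls were higher, and without the mean-variance trend 199 were higher and 517 lower (27.79% higher). The median over all probe sets, which include the dim ones left out of the tests, differed by -0.16 on the log2 scale, imatinib minus vehicle. Relative to that median each difference given here is larger by 0.16. Over the 8145 tested genes the median difference was -0.02, or 0.14 with array medians set equal. Fewer genes were higher whichever of the 4 arrays was left out, which leaves 1 array in a group.

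Most markers of the sorted cells were higher. Of 15 macrophage identity genes, 12 were higher and none lower, and 12 were higher adjusted over the list alone, with a median log2 difference of 0.45 (camera adjusted p = 3.3e-09, against an adjusted p = 0.22 with an estimated correlation). The bacteriolytic enzyme gene Lyz2 rose from 13250 ± 331.5 to 24000 ± 902 (1.81-fold, SD, n = 2), the engulfment receptor gene Mertk rose 2.24-fold, the Fc receptor gene Fcgr3 rose 1.61-fold and the integrin gene Itgam 1.95-fold. Csf1r, the receptor for the macrophage growth factor and itself a target of imatinib, had a log2 difference of 0.12 ± 0.07 (SE, adjusted p = 0.33). The mean over the 15 genes differed by 0.49. A further scaling, chosen after seeing the data, set this mean equal on all arrays and is called the macrophage-marker scale below. It lowers every log2 difference by 0.49, and of 8145 tested genes 101 were higher and 5491 lower on it (1.81% of calls higher). A lower call on it is relative to the macrophage markers and not to the other genes. Camera compares a list with the other genes. At the preset correlation it called 12 lists as higher and 6 as lower there, against 15 and 5 on the deposited scale. The class I, lysosome, and LXR and PPAR lists were no longer called. The unfolded protein response list was called as lower only there (camera adjusted p = 0.020).

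Epithelial transcripts fell together. All 13 epithelial markers were lower, also adjusted over the list alone, with a median log2 difference of -1.85 (camera adjusted p = 6.1e-20, against an adjusted p = 0.22 with an estimated correlation), and all 13 stayed lower under the other scalings. Besides Krt19, the largest decreases were in Epcam (3112 ± 76.4 to 557.1 ± 17.6, SD, n = 2), the keratin gene Krt8 (9513 ± 198.1 to 1860 ± 9.81) and the tight junction gene Cldn7 (2172 ± 170.2 to 407.7 ± 43.7). The Gapdh 3' to 5' ratio was also lower with imatinib, as given above. Its 5' signal was higher by 0.30 on the log2 scale, and its 3' signal differed by -0.05.

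**Figure D1:**
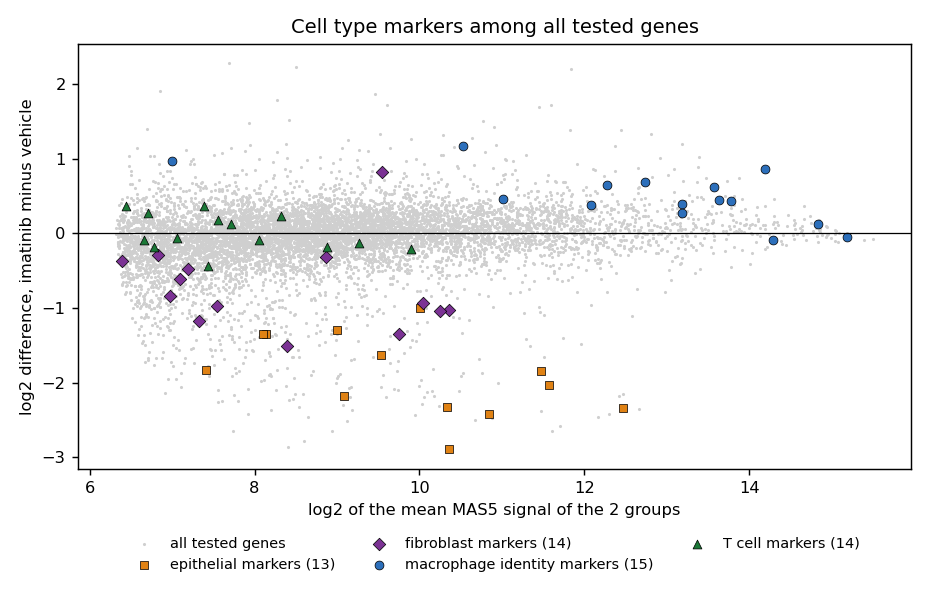
Log2 difference between imatinib and vehicle (vertical axis) against the log2 of the mean signal (horizontal axis) for the 8145 tested genes, with members of 4 fixed marker lists coloured. All 13 epithelial markers lie below 0 (median -1.85) and 12 of the 15 macrophage identity genes were higher (median 0.45), with a median of -0.04 on the macrophage-marker scale.

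Fibroblast markers were lower in part. Of 14 fibroblast genes, 7 were lower and 1 higher (9 and 1 adjusted over the list alone), with a median log2 difference of -0.88 (camera adjusted p = 2.0e-05, against an adjusted p = 0.22 with an estimated correlation). The collagen-modifying genes Loxl1 (-1.51 ± 0.17, SE) and Pcolce (-1.35 ± 0.13), Col1a1 (-1.17 ± 0.35) and the matrix gene Sparc (-1.04 ± 0.10) fell, while Serpinf1 rose 1.76-fold. Of the 4 smooth muscle genes tested, Acta2 was lower (log2 difference -0.82), and of 9 endothelial genes none passed the test (limma, 0 at an unadjusted p under 0.05; Esam -0.01, or 0.15 with array medians set equal, and Kdr 0.03). In the list of GIST and interstitial cells of Cajal, 3 of 8 genes were lower, and the list was not called (median -0.17, camera adjusted p = 0.22). These were Kit, whose signal fell from 1041 ± 87.8 to 655.4 ± 48.8 (SD, n = 2, log2 difference -0.64, adjusted p = 0.0032), Edn3 (-0.91) and Elovl6 (-0.63). Of 6 tyrosine kinases that imatinib inhibits, Ddr1 (-1.89), Pdgfrb (-0.97) and Kit were lower and Abl1 was higher (0.46, or -0.02 on the macrophage-marker scale). Csf1r (0.12) was among the 2 not called. Pdgfrb is also in the fibroblast list and Kit in the GIST list, and Ddr1 fell by about as much as the epithelial median (-1.85). Their falls cannot be told apart from less RNA of other cells. The kinase list was not called (camera adjusted p = 0.12). It was lower with array medians set equal (camera adjusted p = 0.037 at the preset correlation, against an adjusted p = 0.39 with an estimated correlation on the deposited scale).

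Markers of other leukocytes did not move as one. Of 14 T cell genes none passed the gene test (limma, 0 at an unadjusted p under 0.05; Zap70 -0.21 and Cd3g -0.14, or 0.03 with array medians set equal). The T cell list's median was -0.08 with a mean of 0.01 and an upward camera direction (adjusted p = 0.85), and its median was 0.09 both under quantile normalization and with array medians set equal. Among 10 B and plasma cell genes, Cd22 (1.79-fold) and Cd79b (1.30-fold, log2 -0.11 on the macrophage-marker scale) were higher and Ighm was lower (log2 difference -0.62). Their median was -0.08 and their mean -0.01 with an upward camera direction (adjusted p = 0.85), and the median was 0.04 under quantile normalization. Of 10 NK and cytotoxic genes, Gzma (1.45-fold), Klrd1 (1.38-fold) and Ccl5 (1.27-fold) were higher (4 genes adjusted over the list alone), with a list median of 0.27 (-0.22 on the macrophage-marker scale). The camera adjusted p was 0.029, with an adjusted p = 0.26 with an estimated correlation and 0.062 with array medians set equal. Of 13 dendritic cell genes, Cd209a (2.80-fold), the cytokine receptor gene Flt3 (2.21-fold) and Kmo (1.61-fold) were higher (5 genes adjusted over the list alone). The dendritic list median was 0.28 (-0.21 on the macrophage-marker scale; camera adjusted p = 0.0086, against an adjusted p = 0.22 with an estimated correlation). Of 8 monocyte genes, F13a1 (1.91-fold), S100a4 (1.51-fold) and Ms4a6c (1.23-fold) were higher, and the list was not called (median 0.03, or -0.46 on the macrophage-marker scale, adjusted p = 0.27). On that scale the genes higher and lower were 0 and 7 for T cells, 1 and 7 for B and plasma cells, 0 and 1 for NK and cytotoxic cells, 1 and 3 for dendritic cells and 1 and 5 for monocytes. Too few members passed the signal filter to test 5 marker lists. Among these, S100a8 and Csf3r were the 2 higher of 4 neutrophil genes and Pf4 was the 1 higher of 3 erythroid and platelet genes, while the mast cell genes Gata2 (0.02) and Cpa3 (-0.02) and the eosinophil gene Prg2 (0.83, adjusted p = 0.060) did not pass.

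Genes associated with alternative (M2) activation of macrophages rose in part. Mrc1, the mannose receptor, went from a signal of 4067 ± 74.9 to 10320 ± 612.6 (SD, n = 2), a 2.52-fold increase (log2 difference 1.34 ± 0.08, SE, adjusted p = 9.0e-07). The galactose-type lectin genes Clec10a and Mgl2 rose 2.38-fold and 1.79-fold, Retnla (the secreted protein RELM-alpha) 2.16-fold and Il10, an anti-inflammatory cytokine, 1.70-fold. In all, 10 of 18 tested members were higher and none lower (11 higher adjusted over the list alone), with a median log2 difference of 0.68, or 0.20 on the macrophage-marker scale, where 5 were higher and 2 lower. The camera adjusted p was 9.9e-09, against an adjusted p = 0.22 with an estimated correlation. Tgfb1 had a log2 difference of 0.33 ± 0.16 (adjusted p = 0.21), which was -0.16 on the macrophage-marker scale. Arg1, the arginase of alternative activation, lay below the signal filter and was not tested, with signals of 86.2 and 90.4 on the vehicle arrays and 29.8 and 11.8 on the imatinib arrays. Without the filter its log2 difference was -1.21 ± 0.28 (SE, limma adjusted p = 0.051). Epithelial markers were lower by a median of -1.85 and macrophage identity genes higher by 0.45 on the same arrays.

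Genes of classical (M1) activation rose in part. Of 20 tested members, 9 were higher and none lower (11 and 2 adjusted over the list alone), with a median of 0.30, or -0.19 on the macrophage-marker scale, where 2 were higher and 9 lower (camera adjusted p = 3.3e-05, against an adjusted p = 0.22 with an estimated correlation). The prostaglandin synthase gene Ptgs2 rose 1.98-fold, the inflammatory cytokine gene Il1b rose from 10350 ± 471.4 to 16910 ± 708.9 (1.63-fold, SD, n = 2), the lipopolysaccharide receptor gene Tlr4 rose 1.42-fold and Cxcl9 rose 1.31-fold (log2 -0.10 on the macrophage-marker scale). Several hallmark genes did not pass the test: Tnf (log2 difference -0.10, or 0.06 with array medians set equal), Cd40 (0.07), Cd86 (0.24), Il12b (0.37), Il6 (0.56) and Cd80 (0.66, limma adjusted p = 0.059). Of these, Cd80, Cd86 and Il6 passed as higher with array medians set equal, and Cd80 also did under quantile normalization. Cd274, a member of the list of inhibitory receptors and ligands, did not pass either (0.24). On the macrophage-marker scale Cd40 (-0.41), Cd86 (-0.24), Cd274 (-0.24) and Il12b (-0.12) were negative. Tnf, already negative on the deposited scale, passed as lower there, as did Cd40 and Cd86. The inducible nitric oxide synthase gene Nos2 had signals of 4.31 or lower on all 4 arrays and was not tested.

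**Figure D2:**
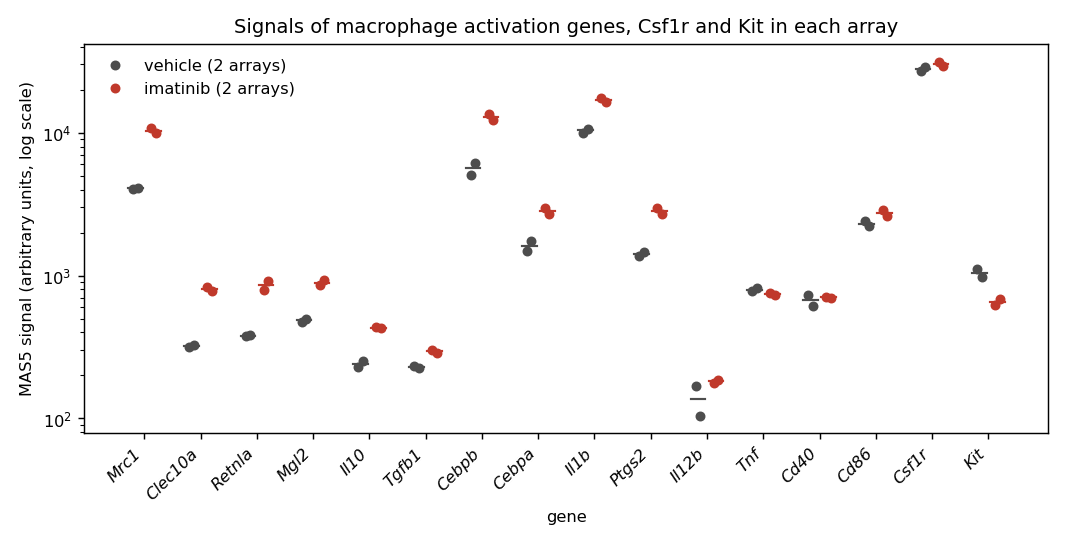
MAS5 signal on a log axis for 16 genes in each of the 2 vehicle and 2 imatinib arrays (points) with the mean of each group (line). Mrc1, Clec10a, Retnla, Mgl2, Il10, Cebpb, Cebpa, Il1b and Ptgs2 passed the test as higher and Kit as lower, while Tgfb1, Il12b, Tnf, Cd40, Cd86 and Csf1r did not pass.

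Some transcription factor, chemokine and receptor genes were higher. Cebpb, a C/EBP factor of macrophage activation, rose from 5628 ± 757.2 to 12910 ± 858.1 (2.30-fold, SD, n = 2, adjusted p = 1.0e-05), Cebpa rose 1.74-fold, Id2 1.83-fold and the nuclear receptor gene Nr4a1 1.79-fold. Gata6, a factor of peritoneal macrophages that epithelium also expresses, was lower (log2 difference -0.97 ± 0.29, SE). Of 17 members of the C/EBP and macrophage transcription factor list, 6 were higher and 1 lower (9 and 2 adjusted over the list alone), with a median of 0.34, or -0.14 on the macrophage-marker scale (camera adjusted p = 3.3e-05, against an adjusted p = 0.22 with an estimated correlation). On that scale 4 were higher and 8 lower, against 5 and 9 of the chemokines, 1 and 11 of the chemokine and cytokine receptors and 3 and 8 of the NF-kappaB targets. Of 18 chemokines, 10 were higher and 1 lower (11 and 3 adjusted over the list alone; median 0.31, or -0.18 on the macrophage-marker scale; camera adjusted p = 9.2e-05, against an adjusted p = 0.22 with an estimated correlation). The neutrophil attractant genes Cxcl1 (2.52-fold) and Cxcl2 (1.63-fold), the monocyte attractant gene Ccl2 (1.82-fold), Pf4 (1.80-fold) and Ccl6 (1.80-fold) rose, and the stromal chemokine gene Cxcl12 fell by 0.82 on the log2 scale. Of 23 chemokine and cytokine receptors, 11 were higher, among them Cxcr4 (2.61-fold), Csf3r (1.62-fold), Il17ra (1.59-fold) and Il6ra (1.54-fold). Adjusted over the list alone, 14 were higher (median 0.32, or -0.17 on the macrophage-marker scale; camera adjusted p = 3.2e-06, against an adjusted p = 0.22 with an estimated correlation). Of 20 NF-kappaB targets, 9 were higher (12 adjusted over the list alone), including the maturation marker gene Cd83 (2.03-fold) and the feedback inhibitor gene Tnfaip3 (1.95-fold). The median was 0.26, or -0.23 on the macrophage-marker scale (camera adjusted p = 5.5e-06, against an adjusted p = 0.22 with an estimated correlation).

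Genes for the uptake and breakdown of apoptotic cells were higher in part. On the macrophage-marker scale, where 5491 of all 8145 tested genes were lower, 4 uptake genes were higher and 6 lower, and 0 lysosome genes higher and 15 lower. Camera at the preset correlation still called the uptake list as higher than other genes there (adjusted p = 4.6e-06), and did not call the lysosome list (adjusted p = 0.67). Of 20 uptake genes, 11 were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.31, or -0.18 on the macrophage-marker scale (camera adjusted p = 3.3e-07, against an adjusted p = 0.22 with an estimated correlation). Cd93 (2.42-fold), Mertk, Cd300a, a receptor for phosphatidylserine (1.96-fold), and the scavenger receptor gene Scarb1 (1.91-fold) rose, and the bridging protein gene Mfge8 fell by 0.57 on the log2 scale. Of 22 lysosome genes, 8 were higher (8 adjusted over the list alone), among them the protease genes Lgmn (1.53-fold), Ctsl (1.53-fold), Ctsa (1.42-fold) and Ctsb (1.29-fold, log2 -0.12 on the macrophage-marker scale). The lysosome median was 0.16, or -0.33 on the macrophage-marker scale (camera adjusted p = 9.2e-05, against an adjusted p = 0.39 with an estimated correlation). Among 17 LXR and PPAR lipid handling genes, the haem oxygenase gene Hmox1 (2.14-fold), the scavenger receptor gene Cd36 (1.47-fold) and the cholesterol exporter genes Abcg1 (1.44-fold) and Abca1 (1.35-fold, log2 -0.05 on the macrophage-marker scale) were higher (5 higher and 1 lower adjusted over the list alone). That list had a median of 0.14, or -0.35 on the macrophage-marker scale, where 1 was higher and 12 lower. Its camera adjusted p was 0.0496, with an adjusted p = 0.28 with an estimated correlation, 0.11 under quantile normalization and 0.062 with array medians set equal. Of 11 inhibitory receptors and ligands, Cd300a, Sirpa (1.56-fold) and Vsir (1.30-fold, log2 -0.11 on the macrophage-marker scale) were higher and Lgals3 was lower (-0.31). Adjusted over the list alone 5 were higher and 1 lower (median 0.36, or -0.13 on the macrophage-marker scale with 1 higher and 3 lower; camera adjusted p = 0.0045, against an adjusted p = 0.26 with an estimated correlation).

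Immediate early and heat shock genes, which tissue dissociation is known to induce, formed the list with the largest share of higher genes on the deposited scale. With array medians set equal 19 of 24 were higher, against 12 of 15 macrophage identity genes. Of 24 genes, 20 were higher and none lower (21 adjusted over the list alone), with a median of 0.57, or 0.09 on the macrophage-marker scale, where 10 were higher and 7 lower (camera adjusted p = 6.1e-20, against an adjusted p = 0.22 with an estimated correlation). The chaperone gene Dnajb1 rose from 3074 ± 85.7 to 8100 ± 754.5 (2.61-fold, SD, n = 2), and Klf2 (2.48-fold), Fosb (2.07-fold) and Btg2 (2.01-fold) rose. The macrophage identity and epithelial medians on these arrays were 0.45 and -1.85.

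Metabolic and cell cycle genes were lower in part, on arrays where the epithelial median was -1.85, the fibroblast median -0.88 and the Gapdh 3' to 5' ratio lower with imatinib. Of 23 cell cycle genes, 5 were lower (6 adjusted over the list alone): the mitotic genes Bub1 (-1.02 ± 0.16, SE) and Cdc20 (-0.85 ± 0.12) and the replication genes Mcm4 (-0.80 ± 0.13), Rrm2 (-0.78 ± 0.10) and Mcm2 (-0.60 ± 0.15). Their list median was -0.30 (camera adjusted p = 0.0017, against an adjusted p = 0.22 with an estimated correlation). Of 15 glycolysis genes, Pfkp (-0.63), Hk1 (-0.45), Pgk1 (-0.40), Aldoa (-0.33) and Ldha (-0.27) were lower (6 adjusted over the list alone), with a median of -0.25. The glycolysis list had a camera adjusted p = 0.0026, an adjusted p = 0.22 with an estimated correlation and 0.056 with array medians set equal. Of 25 oxidative phosphorylation genes, Cycs, the cytochrome c gene (-0.79), Cox5a (-0.41), Uqcrc2 (-0.40), Cox7a2 (-0.37) and Cox5b (-0.26) were lower (9 adjusted over the list alone), with a median of -0.17. That list had a camera adjusted p = 0.00075, an adjusted p = 0.47 with an estimated correlation and 0.11 with array medians set equal. Among 16 cholesterol synthesis genes, Fdft1 (-0.85), Idi1 (-0.81) and Hmgcs1 (-0.39) were lower (4 adjusted over the list alone; list not called, median -0.21, camera adjusted p = 0.088). Of 13 hypoxia and angiogenic genes, Ndrg1 (-1.60), Higd1a (-1.10) and Egln3 (-1.004) were lower and Ddit4 was higher (0.60). The counts depended on the scaling. With array medians set equal 4 cell cycle, 1 glycolysis and 1 oxidative phosphorylation genes were lower. Under quantile normalization 5, 5 and 10 were, and on the macrophage-marker scale 20, 15 and 25 were. The hypoxia list was not called (adjusted p = 0.60), and its median (0.03, or -0.46 on the macrophage-marker scale) differed in sign from its mean (-0.20) and its downward camera direction.

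Few antigen presentation and interferon genes passed the test. The simulated share of 19% called at 0.5 does not carry over to these lists, since far fewer genes changed in the simulation than were called here. Bright genes with smaller changes passed, such as Ifi30 (0.42, limma adjusted p = 0.0052) and Gbp7 (0.38, limma adjusted p = 0.0071). Of 14 class I genes only Pdia3 was higher (1.35-fold, log2 -0.06 on the macrophage-marker scale; 1 adjusted over the list alone), with a list median of 0.13, or -0.36 on that scale, where 12 were lower. The class I list had a camera adjusted p = 0.046, an adjusted p = 0.39 with an estimated correlation, 0.50 under quantile normalization and 0.062 with array medians set equal. Of 13 class II genes, Ciita, the class II transactivator gene (log2 difference 0.58), H2-DMa (1.38-fold, log2 -0.02 on the macrophage-marker scale) and Ifi30 (1.33-fold, log2 -0.07) were higher, and the list was not called (median 0.08, or -0.41 on that scale, adjusted p = 0.12). Of 9 interferon-gamma-induced GTPases, Gbp3 (1.32-fold, log2 -0.09 on the macrophage-marker scale) and Gbp7 (1.31-fold, log2 -0.10) were higher (median 0.08, or -0.40 on that scale, adjusted p = 0.070). Of 23 type I interferon response genes none passed the test in limma (4 at an unadjusted p under 0.05; Bst2 -0.21, and Rsad2 -0.01 or 0.15 with array medians set equal). Their median was -0.03 with an upward camera direction (adjusted p = 0.85). It was 0.13 with array medians set equal, where 2 of the 23 were higher, and -0.52 on the macrophage-marker scale, where 20 of the 23 were lower. Of 16 unfolded protein response genes, Herpud1 was higher (1.37-fold, log2 -0.03 on the macrophage-marker scale) and Creld2 (-0.55), Atf4 (-0.44) and Manf (-0.28) were lower, with a median of -0.04 (camera adjusted p = 0.39). With array medians set equal the median was 0.12, with 1 gene higher (Herpud1) and 0 lower. On the macrophage-marker scale the median was -0.53, and camera at the preset correlation called this list as lower (adjusted p = 0.020). Of 16 matrix remodelling genes, the proteases Mmp13 (log2 difference 0.89), Mmp2 (0.58) and Mmp12 (0.56) were higher and Timp3 (-1.29), Sparc and Fn1 (-0.58) were lower, with a median of 0.11, or -0.37 on the macrophage-marker scale (adjusted p = 0.25).

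**Figure D3:**
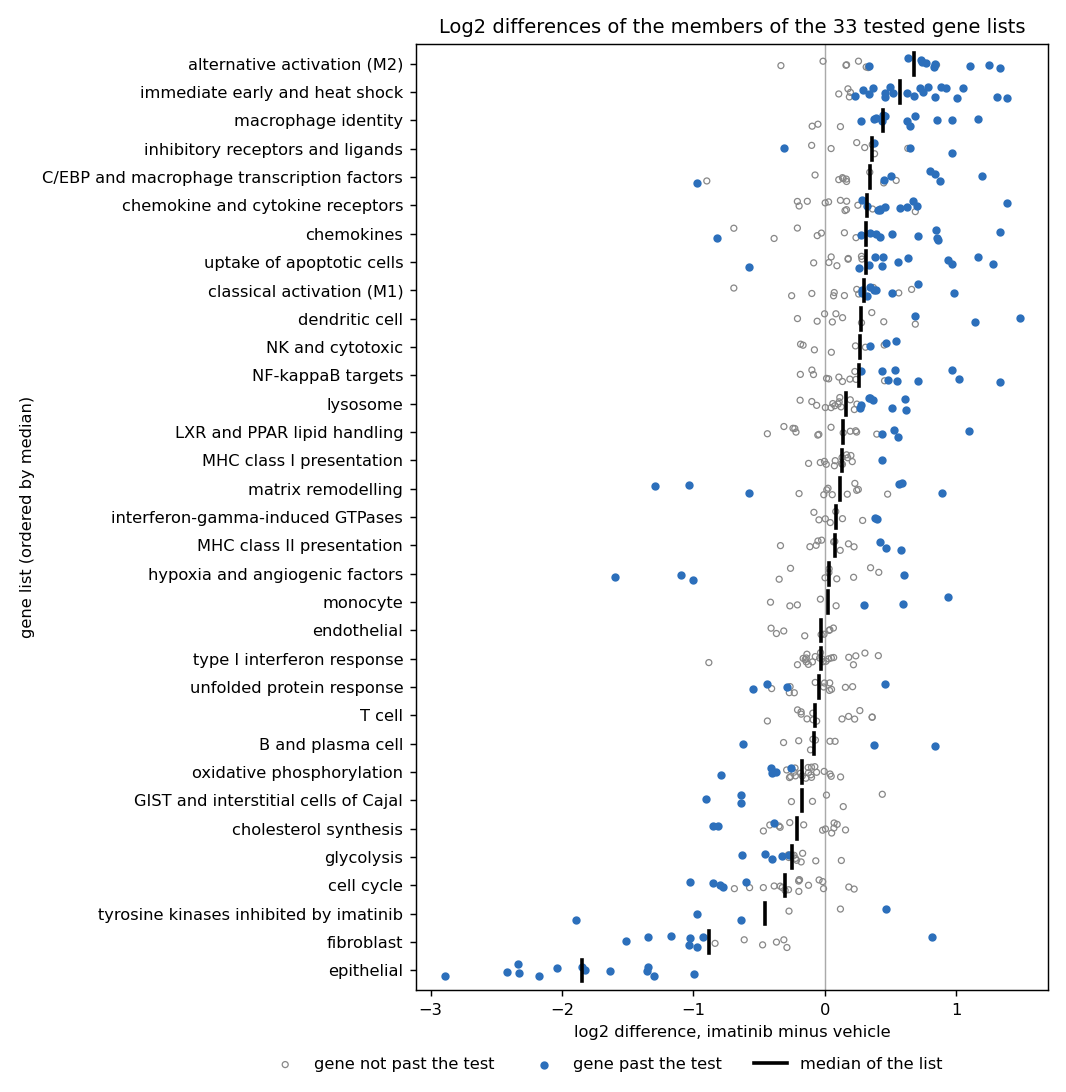
Log2 difference between imatinib and vehicle (horizontal axis) of each tested member (points, filled where the gene passed the test) of the 33 gene lists with at least 5 tested members, with the list median (black bar). Epithelial (median -1.85) and fibroblast (-0.88) genes lie lowest, and alternative activation (0.68) and immediate early genes (0.57) highest, while on the macrophage-marker scale those 4 medians are -2.33, -1.37, 0.20 and 0.09 and other positive medians turn negative.

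Of the 33 lists tested, camera called 15 as higher and 5 as lower at the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.22, 3 at an unadjusted p under 0.05) and fry called 22. The epithelial list had an estimated correlation of -0.03, below the preset 0.01. Its unadjusted camera p was still 0.0097, against 1.9e-21 at the preset correlation. With 2 residual degrees of freedom, the estimated-correlation results cannot tell whether correlation between genes accounts for the list calls. Without the mean-variance trend the number of called members fell from 12 to 6 for macrophage identity, 9 to 3 for classical activation, 11 to 3 for receptors, 11 to 6 for chemokines, and 7 to 4 for transcription factors. It fell from 9 to 5 for NF-kappaB targets, 12 to 7 for uptake, 8 to 1 for lysosome and 20 to 12 for immediate early genes. It also fell from 5 to 1 for glycolysis, 5 to 1 for oxidative phosphorylation, 5 to 3 for the cell cycle, 4 to 0 for the unfolded protein response, and 3 to 1 each for class II, monocytes and NK cells. For the GTPases it fell from 2 to 0, for class I from 1 to 0 and for neutrophils from 2 to 1. It was 9 of 10 for alternative activation and 12 of 13 for epithelium. Members higher and lower on the macrophage-marker scale, for lists not given above, were 3 and 4 for macrophage identity, 1 and 13 for fibroblasts, 0 and 5 for endothelium, 0 and 4 for GIST and 0 and 4 for the kinases. They were 0 and 8 for class II, 0 and 5 for the GTPases, 0 and 14 for the unfolded protein response, 1 and 10 for matrix remodelling, 0 and 10 for cholesterol synthesis and 0 and 8 for hypoxia. Among the lists not called, members higher and lower adjusted over the list alone were 3 and 0 for class II, 0 and 0 for type I interferon, 2 and 0 for the GTPases, 0 and 4 for cholesterol synthesis, 3 and 3 for hypoxia, 1 and 4 for the unfolded protein response and 5 and 3 for matrix remodelling. They were 1 and 3 for the kinases, 3 and 1 for monocytes, 0 and 0 for T cells, 2 and 1 for B cells, 0 and 3 for GIST and 0 and 0 for endothelium. In the lists too small to test they were 2 and 0 for neutrophils, 0 and 0 for mast cells, 1 and 0 for eosinophils, 0 and 2 for smooth muscle and 1 and 0 for erythroid cells and platelets. If each group was 1 pool, as the design text describes, differences between pools and effects of the drug were not separated.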

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

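The tests of pool handling, of array scaling and of other splits of the arrays, and the macrophage-marker scale itself, were chosen only after the results were seen. So were the checks of each macrophage-marker count with 1 array left out, at the upper bound of the marker mean and against the markers themselves. Control probe sets and probe sets without a single gene symbol, which the gene comparison did not use, also differed between the groups. The 3' probe set of 18S ribosomal RNA was higher with imatinib by 0.50 on the log2 scale (0.01 on the macrophage-marker scale). Its 5' probe set differed by 0.11. The 5' probe sets of beta-actin and Gapdh were higher by 0.32 and 0.30, and differed by -0.17 and -0.19 on the macrophage-marker scale, while their 3' probe sets differed by -0.08 and -0.05. The 9 bacterial and phage spike-in probe sets were lower, by -0.12 to -0.46. Of the probe sets that carry several symbols, 55 were higher and 29 lower with imatinib, and of those that carry none, 36 and 41 (91 higher in all).

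The 13 epithelial markers were lower with imatinib. Array scaling does not account for this, since the median was -1.68 or lower under quantile normalization and with array medians set equal. Nor does an effect on dim genes, since 0 of 10000 random lists matched on mean signal had a median as low (percentile 0). A second list of 33 intestinal epithelial genes, written before its values were seen and sharing 0 genes with the fixed lists, had 21 of 24 tested members lower and a median of -1.55, with Ceacam1 falling from 8951 to 2007, Zg16 from 4993 to 1870 and Fabp2 from 1758 to 336.7. This is consistent with less epithelial RNA in the imatinib pool, which a macrophage gate should have largely removed from both pools, while an effect of imatinib on the amount of epithelium stays open as untested.

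The alternative activation genes were higher with imatinib, with a median of 0.68. The 2 scalings on all probe sets argue against array scaling as the cause. Under quantile normalization 10 members were higher and 0 lower (median 0.61), and with array medians set equal 12 and 0 (median 0.84). The rule set for array scaling also counted the scaling to equal macrophage identity markers, which moves with cell content as well. Only 5 members were higher (with 2 lower) there, so by that rule array scaling cannot be told apart from regulation. Nor can a higher share of macrophage RNA: 5 was exactly the number set beforehand as the bound against it, and the count was 4 to 6 with 1 array left out (4 without imatinib replicate 1 or imatinib replicate 2). The markers themselves spread from -0.10 to 1.16 (SD 0.35), 3 of the 15 were higher on that scale, and 3 members of the list stayed higher at 0.66, the upper 95% bootstrap bound of the marker mean of 0.49. Handling of the pools cannot be told apart from imatinib either, because the design text describes 1 pool per group, and an effect of imatinib stays open.

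The immediate early and heat shock genes were higher with imatinib, with a median of 0.57. A higher share of macrophage RNA cannot be told apart from regulation: with macrophage identity markers set equal 10 of 24 members stayed higher and 7 were lower, while 3 of the 15 markers were higher and 4 lower (one-sided Fisher's exact p = 0.15 across genes, which are not independent replicates). The bound of 5 set beforehand was too low, since the share of higher markers corresponds to 4.8 of 24 members, although the count was 7 to 9 with 1 array left out and 6 at the upper bound of 0.66 for the marker mean. Handling of the pools at digestion and sorting may differ between pools whatever the drug. With the 1 pool per group that the design text describes, it cannot be told apart from an effect of imatinib, which stays open.

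The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 1265 genes past the threshold and the highest of the others gave 0 (2287 against 102 at an unadjusted p under 0.05, limma), so that 1 of the 3 splits gave as many. The other splits put 1 vehicle and 1 imatinib array in each group, so any difference between the real groups widens their residual spread and leaves few calls. A difference between pools would give the same outcome as an effect of imatinib.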

How the results depend on the processing

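All 145 called genes that the text names kept their direction under every alternative fixed in advance that gave them a value (20 of them lack a value under 1 or more, 23 values in all), and 79 also kept their call under each of these; 102 kept it in all 4 fits without 1 array, where the lone array of a group is assumed to vary like the other group. The number of arrays, signals near the filter and the 1 pool per group that the design text describes are all limits here. The macrophage-marker scale was chosen after seeing the data. The cause of the changes below was not tested, except where the construction gives it. Genes higher numbered 356 with no filter and those lower at least 2-fold 171 with a 60th percentile filter, which change the genes tested. Higher and lower at least 2-fold were 30 and 180 with the larger pseudocount, which shrinks folds. Genes higher numbered 1050 (90 at least 2-fold) with array medians set equal, 853 (76) for each probe set on its own and 199 with no variance trend. Treat against 1.2-fold, a stricter question, gave 144 higher and 372 lower. On the macrophage-marker scale, which lowers all differences by 0.49, 101 were higher and 5491 lower (11 and 826 at least 2-fold). Leaving out 1 array gave 291 to 476 higher, 506 to 664 lower, 50 to 64 and 292 to 373 at least 2-fold, and 17 to 21 lists; 349 were higher without vehicle replicate 1 and 291 without imatinib replicate 1. Camera with an estimated correlation, which rests on 2 residual degrees of freedom, called 0 lists (3 at an unadjusted p under 0.05), against 22 by fry. With the replicate number as a block (replicate block), 430 genes were higher, 635 lower and 18 lists called; arrays that share a number did not deviate together (correlation -0.057). Treat and the robust prior give no list test, and single probe sets none for lists or named genes.

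Changes of direction concerned results that were not called, or the macrophage-marker scale. The camera direction of the type I interferon list turned at medians of -0.021 (60th percentile filter) and -0.028 (quantile normalization). It also turned without vehicle replicate 2 (-0.10) and without imatinib replicate 1 (-0.036), with medians of -0.10 to 0.052 without 1 array. Fry, a different test, gave a downward direction at the main median of -0.033. For the B and plasma cell list the camera direction turned at -0.091 (no filter), -0.081 (no variance trend) and -0.13 (without vehicle replicate 1), with -0.13 to -0.024 without 1 array. Fry gave a downward direction there at the main median of -0.081. The T cell list turned at -0.14 (60th percentile filter) and -0.15 (without vehicle replicate 2), with -0.15 to 0.081 without 1 array, and the endothelial list at 0.069 (quantile normalization). Quantile normalization gave 0.069 for Esam and 0.16 for Cpa3. Array medians set equal gave 0.062 for Tnf, 0.025 for Cd3g, 0.15 for Esam, 0.15 for Rsad2 and 0.14 for Cpa3, and the mean of all probe sets gave 0.080 for Rsad2. Without 1 array, values ran from -0.045 to 0.19 for Cd40, -0.46 to 0.045 for Zap70, -0.025 to 0.012 for Esam, -0.24 to 0.31 for Kdr, -0.12 to 0.097 for Rsad2, -0.089 to 0.12 for Gata2 and -0.22 to 0.19 for Cpa3. On the macrophage-marker scale the directions of the lists of class II (-0.41), class I (-0.36), type I interferon (-0.52), interferon-gamma GTPases (-0.40), GIST (-0.66) and endothelial genes (-0.51) turned. Genes that turned negative on it were Tgfb1 (-0.16), Cxcl9 (-0.097), Il12b (-0.12), Cd40 (-0.41), Cd86 (-0.24), Cd274 (-0.24), Csf1r (-0.37), Ctsb (-0.12), Abca1 (-0.051), Herpud1 (-0.030), Vsir (-0.11), Abl1 (-0.022), Ms4a6c (-0.19), Cd79b (-0.11), Klrd1 (-0.024), Ccl5 (-0.14), Kdr (-0.45), H2-DMa (-0.018), Ifi30 (-0.070), Pdia3 (-0.055), Gbp3 (-0.088), Gbp7 (-0.10) and Gata2 (-0.47).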

Other observations

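The comparison of the 2 activation lists, the gene families and the T cell test were chosen only after the results were seen, as were the genes named here beyond those of the report. Genes whose symbols begin with Cd and a number and C-type lectin genes were overrepresented among the higher genes. Of 64 tested Cd genes, 21 were higher and 3 lower (one-sided Fisher's exact test against all tested genes, adjusted p = 1.0e-07 over 184 tests in 92 families), with a median of 0.20 that was -0.28 on the macrophage-marker scale, where 8 were higher and 24 lower. Of 13 Clec genes, 6 were higher and 2 lower (adjusted p = 0.010), with a median of 0.69, or 0.20 on the macrophage-marker scale, where 5 were higher and 4 lower. Besides Clec1b, Clec4n and Clec10a, these were Clec7a, the beta-glucan receptor gene (8514 ± 556 to 14230 ± 842.3, SD, n = 2), Clec4a2 (1.82-fold) and Clec4b1 (2.00-fold), while Clec2d (-0.57) and Clec2h (-1.85) were lower. No family passed the test among the lower genes. On these arrays macrophage identity genes were higher by a median of 0.45.

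The alternative activation list had a higher mean log2 difference (0.57, 18 genes) than the classical activation list (0.28, 20 genes). The difference of 0.30 had a two-sided permutation p = 0.030 across genes, which are not independent replicates, with 100000 permutations. The signal filter left out Arg1 of the alternative list (log2 difference -1.21) and other members of both lists. Without the filter the means were 0.43 (23 genes) and 0.18 (24 genes), and the difference of 0.25 had a two-sided permutation p = 0.094 across genes, so the comparison did not keep its side of 0.05.

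The rise of Cd4, from a signal of 48.8 to 362.7, could come from T cells in the imatinib pool. The T cell list argues against this, with a median of -0.076 and 0 of 14 genes higher in limma (0 at an unadjusted p under 0.05). A second hypothesis was that Cd4, Adamdec1, Clec1b and Spic rose because the imatinib pool may hold more tissue-resident macrophages. A list of 20 resident macrophage genes, written before its values were seen, with 3 of its 15 tested genes also in the fixed lists, had 6 genes higher, among them Igf1 (1.78-fold) and P2ry12 (1.47-fold), and Lyve1 lower (-0.44). Its median of 0.32 differed from that of the macrophage identity genes by -0.13 (95% bootstrap interval over genes -0.46 to 0.08), where 0.3 or more, with 5 members higher, had been set as what the hypothesis would need and less than 0.1 as counting against it.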
